A study of Mus musculus with 3 samples.

How the data were processed

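RNA was measured in 3 sorted populations of mouse bone marrow cells, MPPs, GFP- HSCs and GFP+ HSCs, with 1 library per population and therefore 3 libraries in all. Per the labels' protocols, RNA was extracted with TRIzol and a PicoPure kit, cDNA was made with the SMART-seq v4 Ultra Low Input kit and libraries with a low input library kit. That chemistry copies full-length transcripts from few cells by PCR, without molecular identifiers and without marking the strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, STAR, DESeq2 and the build mm10 were used. Versions, the annotation, the counting tool and whether a column pools several libraries are not given in the sources used here.

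The deposited values are 1 table of normalized counts per gene, held by the authors as whole numbers, and they were treated as a score because the reads behind them could not be recovered. All values in the 3 columns were whole, and every whole number from 0 to 50 occurred in each column, with no step that would mark 1 read. The ratio of each column to the geometric mean over the columns had a median of 0.987 to 1.02 over genes above 0 in all libraries, as scaling by size factors gives. The factors were not given, so the depth per library is unknown and no counting interval or lower limit of detection was computed. Counting intervals had been planned for the case that reads could be recovered, and were not made. A level of 0 is described as listed at 0. Column names gave the population of each library, with neg and pos read as the GFP- and GFP+ HSCs. The table had 23420 rows. In 27 rows a date stood in place of a symbol, as spreadsheets make of some gene names; these rows held 0.212% of the summed levels and were left out, among them 4 that shared a date with another row. That left 23393 rows, of which 6536 were 0 in all libraries. There were 0 rows for genes of the mitochondrial genome, and 7 of 8 haemoglobin rows were 0 in all libraries, as was the ribosomal protein gene Rpl26, which cells generally express, so a listed 0 need not mean absence. By symbol or synonym, 23234 names matched RefSeq, which also gave the GRCm38 coordinates printed here. Symbols are printed as the table gives them; Igj, Sdpr, Ccdc135, Pyhin1 and Hist1h1b are now called Jchain, Cavin2, Drc7, Ifi209 and H1f5.

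Ratios were computed as log2 of (level + 5) in both libraries, which understates differences of low genes. Folds printed for single genes are ratios of the levels themselves, and folds of lists are medians on the log2 scale turned back. Genes with a mean level of at least 50 over the 3 libraries were compared, 11951 in number, holding 99.6% of the summed levels. With 1 library per population there was no test and no p-value. Genes at least 2-fold apart were counted for 3 comparisons, and Spearman and Pearson correlations were taken across genes. Genes 2-fold apart in the same direction at both steps of the order MPP, GFP- HSC, GFP+ HSC were counted and set beside the number that independent lists share and beside 100 simulated sets of unchanged libraries with the GFP- library in common. Their noise was normal on the log2 scale, with its width taken in each of 20 bins of mean level from the median absolute spread of GFP+ against GFP- HSCs, so variation between repeated sorts is left out. Before the data were examined, 33 gene lists were fixed from general knowledge. They cover stem cell, progenitor and lineage genes, cell cycle, quiescence, metabolism, ribosomes, interferon and stress responses, markers of other cell types, and sort, sex and housekeeping genes. The median of each list with at least 5 members past the filter, 29 lists in all, was placed among medians of 10000 random lists of the same size matched on mean level in 20 bins, and a list stood apart outside percentiles 2.5 to 97.5. Of 87 list medians, 60 did. The B cell, T and NK cell, mitochondrial genome and Pdzk1ip1 neighbour lists were too small and are given as values.

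Named genes followed a rule fixed with the lists. It took the 10 highest and 10 lowest ratios of each comparison among genes with a mean of at least 100, leaving out predicted or unnamed models, and 8 sort and progenitor genes. It also took up to 4 members of each list that stood apart, and the 5 rising and 5 falling genes with the largest total ratio across the order. Other members are named where a whole list is described or where a gene went against its list, and those were chosen after their values were seen. Some genes that the rule names are not reported here. The alternatives were pseudocounts of 1 and 20, minimum means of 10 and 200 or none, rescaling to the same total or upper quartile, removal of the abundance trend by lowess, a 4-fold threshold, random lists without matching, list means, and lists without shared members. Removal of the trend on transcript length and GC content, random lists also matched on length and GC content (from the 100 nearest genes) and a filter on the 2 libraries compared were added after the data were seen. Length and GC content came from the longest GENCODE M21 transcript of a symbol, found for 99.3% of genes past the filter.

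The calculation was tested on simulated libraries drawn from the real levels, with known differences, counting noise and an assumed spread of 0.1 on the natural log scale between libraries put in. Counting noise was drawn as if each normalized count were a read. The depth is unknown and PCR duplicates were left out, so the shares below rest on that assumption. For GFP+ against GFP- HSCs, run on 11964 genes, 94% of genes simulated at 2.5-fold and 2% of those at 1.5-fold passed the 2-fold rule. Of 100 simulated lists of 30 genes with no shift, 6 stood apart, and 100 of 100 did with a shift of 0.3. For GFP- HSCs against MPPs, run on 11961 genes, the shares were 98.0% and 2%, with 4 and 100 lists. For GFP+ HSCs against MPPs, run on 11980 genes, they were 96% and 2%, with 7 and 100 lists. Members of the simulated lists were drawn at random and their noise was independent between genes. The shares of lists therefore do not show how often a list whose genes move together would stand apart between repeated libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.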

Results

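RNA was profiled from 3 populations of bone marrow cells of C57BL/6 mice, with 1 library for each population. The populations were sorted by flow cytometry from the LSK compartment, the lineage-negative, Sca-1-positive and c-Kit-positive cells that hold the stem cells and the early multipotent progenitors of the marrow. Hematopoietic stem cells (HSCs) were gated as CD48-negative and CD150-positive and were divided by a GFP reporter for Map17 into a GFP+ and a GFP- fraction. Multipotent progenitors (MPPs), which lie downstream of stem cells and give rise to all blood lineages, were gated as CD48-positive, CD150-negative and GFP-. Map17 is another name of Pdzk1ip1, which encodes a small membrane-associated protein and lies on chromosome 4 from 115088708 to 115093894 (GRCm38, also called mm10). The measured quantity was the normalized count per gene, and the 3 values of a gene are called its levels. The levels summed to 26748600 in MPPs, 25427967 in GFP- HSCs and 25364232 in GFP+ HSCs, after the authors' scaling, so the sequencing depth itself is unknown. Genes with a level above 0 numbered 15484, 15856 and 15748 in the same order, and 11951 genes had a mean level of at least 50 and entered the comparisons. The most abundant transcript was Fos in MPPs, at 154546, and Jun in GFP- and GFP+ HSCs, at 190529 and 180537. There were no replicates, so no difference could be set against a spread between replicates and no test was made. Genes were named and counted by fixed rules of size, and each gene list was placed among 10000 random lists of the same size and expression, as a description of these libraries.

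The genes of the sort markers came first, as a check of the library labels. Slamf1, which encodes CD150 (chromosome 1, 171767131 to 171801184), stood at 17 in MPPs, 2144 in GFP- HSCs and 2219 in GFP+ HSCs. Cd48 (chromosome 1, 171681245 to 171705258) stood at 7744, 168 and 64. Both went the way of the gates. Kit (chromosome 5, 75574987 to 75656722) and Ly6a, which encodes Sca-1 (chromosome 15, 74994877 to 74998031), were present in all 3 libraries, at 23579, 42967 and 47772 for Kit and at 1767, 2184 and 2702 for Ly6a. Pdzk1ip1 stood at 290 in MPPs, 3673 in GFP- HSCs and 5659 in GFP+ HSCs. It was therefore 1.54-fold higher in the GFP+ than in the GFP- fraction, and 12.7-fold higher in the GFP- fraction than in MPPs. The transcript of the reporter's locus was therefore not restricted to the fraction with the reporter on. Of 4 genes near Pdzk1ip1 that passed the abundance filter, Tal1 stood at 820, 2201 and 2000, Stil at 2701, 1338 and 746, Cmpk1 at 4507, 3741 and 3501 and Cyp4b1 at 3, 93 and 107. Procr, which encodes the stem cell marker EPCR (chromosome 2, 155751125 to 155755478), stood at 634, 2807 and 3776. Cd34 (chromosome 1, 194938821 to 194961292) and the cytokine receptor gene Flt3 (chromosome 5, 147330741 to 147400489), both marks of progenitors in the mouse, ran the other way, at 42578, 10319 and 6240 for Cd34 and at 19467, 1253 and 829 for Flt3. The median log2 ratio of these 8 sort and progenitor genes, which go in both directions, was 0.10 for GFP+ against GFP- HSCs, 0.59 for GFP- HSCs against MPPs and 0.81 for GFP+ HSCs against MPPs.

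**Figure D1:**
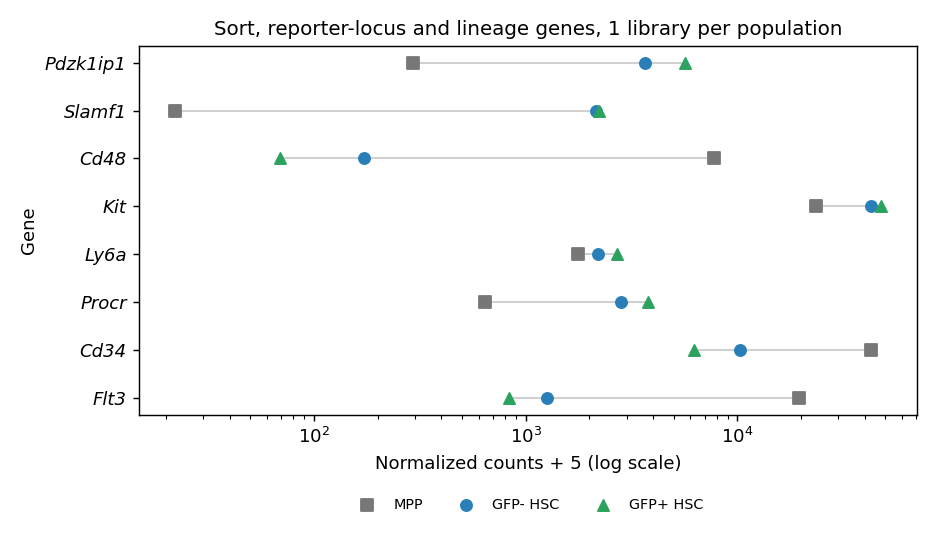
Levels of 8 genes of the sort, the reporter locus and the progenitor state in the 3 libraries; the horizontal axis is the normalized count plus 5 on a log scale, and each point is 1 library. Pdzk1ip1, Slamf1 and Procr lie far lower in MPPs than in either HSC fraction, Cd48, Cd34 and Flt3 far higher, with Cd48 at 7744 in MPPs against 168 and 64 in GFP- and GFP+ HSCs.

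The comparison of GFP+ with GFP- HSCs asked how the reporter divides cells of 1 and the same stem cell gate. The 2 fractions were close, but cell division genes, genes of MPPs and part of the erythroid and megakaryocyte genes were lower in GFP+ HSCs. Genes of the HSC list were slightly higher. All 40 mitosis genes and all 40 S phase genes were lower in GFP+ HSCs, with median ratios of 1.53-fold and 1.43-fold. HSC genes were 1.20-fold higher at the median, with 46 of 53 members higher in GFP+ HSCs. Only 49 genes were at least 2-fold higher and 104 at least 2-fold lower in GFP+ HSCs, out of 11951, and the Spearman correlation across genes was 0.990. The median absolute log2 ratio was 0.14.

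Of the genes farthest apart, those higher in GFP+ HSCs included a pair of transcriptional cofactors at high levels. Ski, which represses TGF-beta target genes, stood at 5247 in GFP+ and 1102 in GFP- HSCs (4.76-fold), and Irf2bp2 stood at 4863 and 1757 (2.77-fold). Gimap3, a member of a family of GTPases of lymphoid cells, stood at 842 and 349 (2.41-fold). Inhba, which encodes a subunit of activin, stood at 229 and 96. Col1a1, a chain of type I collagen, stood at 294 and 22, Igj, the joining chain of secreted immunoglobulins, at 412 and 46, and Ngp, a neutrophil granule protein, at 499 and 165. Smtnl2 (229 and 80), Tmem119 (123 and 47) and Igsf6 (106 and 43) completed the 10 with the highest ratios. Of these 10, Ski and Irf2bp2 (1364 and 5781 in MPPs), Igj, Tmem119 and Igsf6 were lower in GFP- HSCs than in MPPs, and the others were higher. Among the 10 with the lowest ratios, Car1, an erythroid carbonic anhydrase, stood at 459 in GFP+ and 1791 in GFP- HSCs (3.90-fold lower), Pf4, a platelet chemokine, at 331 and 1171 (3.54-fold lower), and Prg2, the eosinophil major basic protein, at 9 and 149. Nkg7, a granule protein of cytotoxic cells, stood at 267 and 928 (3.48-fold lower), and the linker histone gene Hist1h1b at 58 and 220. Ubash3a (42 and 193), Tespa1 (12 and 64) and Nlrc3 (43 and 176), known from lymphocytes, were lower as well, as were Apcdd1 (1 and 34) and the lymphoid enzyme gene Dntt (2 and 18), both near the bottom of the scale. All of these but Car1 and Pf4 were also lower in GFP- HSCs than in MPPs.

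**Figure D2:**
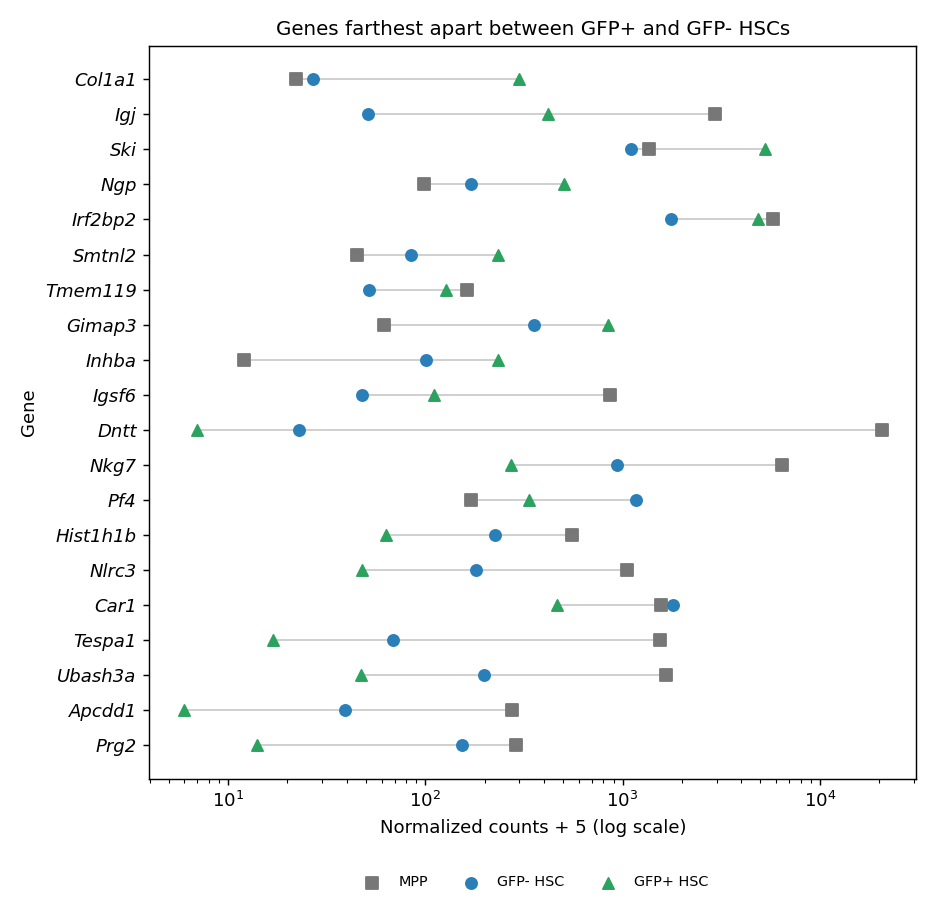
The 10 genes with the highest and the 10 with the lowest ratio of GFP+ to GFP- HSCs among genes with a mean level of at least 100; the horizontal axis is the normalized count plus 5 on a log scale, and each point is 1 library. Col1a1, at 294 in GFP+ and 22 in GFP- HSCs, heads the upper group, and Prg2, at 9 and 149, closes the lower one.

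Among HSC genes, 0 of 53 were 2-fold apart between the 2 HSC fractions, and the median log2 ratio was 0.26, above all 10000 matched random lists. Those lists were matched on mean level only. Of all genes at least 2-fold higher in GFP- HSCs than in MPPs, 76.8% were higher in GFP+ HSCs, by a median of 0.23. The step between the fractions therefore does not set the HSC list apart from other genes high in HSCs. Hoxb5 stood at 618 in GFP+ and 346 in GFP- HSCs, Cdkn1c, an inhibitor of the cell cycle, at 2792 and 1951, and Mllt3 at 7984 and 5559. Of the 7 members that were lower, Vldlr was farthest, at 720 against 1429. Stem cell transcription factors had a median of 0.15, with 24 of 30 higher in GFP+ HSCs, among them Nkx2-3 at 5176 and 3786. MPP genes had a median of -0.55, and 18 of 20 were lower. Plac8 stood at 511 in GFP+ and 1230 in GFP- HSCs, and Mpo, which encodes myeloperoxidase, was level at 2750 and 2758. The medians of S phase and mitosis genes were -0.51 and -0.62, both below every matched random list, though 0 of the 80 passed the 2-fold rule. The replication licensing gene Cdc6 stood at 779 and 1474, E2f8 at 726 and 1456, the mitotic kinase genes Cdk1 and Aurka at 1135 and 1994 and at 730 and 1230, and Cdca3 at 581 and 1083. Quiescence genes were evenly divided, with 13 higher and 13 lower and a median of 0.03, at percentile 76.2 of the random lists.

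Lineage genes did not move as 1 block. Erythroid genes had a median of -0.35, with 15 of 19 lower in GFP+ HSCs, including the erythroid and megakaryocyte transcription factor gene Gata1 (279 and 758) and Ermap (207 and 540). Megakaryocyte and platelet genes had a median of -0.20, with 21 of 31 lower and 5 at least 2-fold lower. Gata1 is also a member of that list, and F2rl2 (124 and 342) and Plek (2128 and 4525) were lower too, whereas Vwf (9964 and 7697) and Mmrn1 (26685 and 19967) were higher in GFP+ HSCs. Myeloid progenitor genes (14 higher, 14 lower, median 0.02) and lymphoid progenitor genes (12 higher, 9 lower, median 0.02) lay within the random range. Interferon response genes had a median of 0.27 with 24 of 30 higher, among them Ifi44 at 2560 and 1833 and Oasl2 at 4309 and 3181. Immediate-early genes, which respond to stress and cell isolation as well as to signals, had a median of -0.19 with 26 of 30 lower. Atf3 was lower at 4702 and 6463, and so was the heat shock gene Hspa1a, which this list also holds, at 1963 and 2950. Nr4a1 was higher, at 60214 and 50260. Cytosolic ribosomal protein genes had a median of -0.19 (59 of 69 lower), ribosome biogenesis genes of -0.13 (27 of 30 lower) and nuclear oxidative phosphorylation genes of -0.24 (75 of 77 lower), with Cox5a at 1746 and 2473 and Ndufa4 at 1706 and 2458. With the trend on transcript length and GC content removed, the ribosomal protein median was -0.12 and the oxidative phosphorylation median -0.13, both still outside the random range.

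Among markers of other cell types, neutrophil genes had a median of 0.88 in 9 members, above all random lists, with 8 higher in GFP+ HSCs. The exception was Padi4, at 2833 and 2959, and the others had small levels. Ltf stood at 323 and 165, Chi3l3 at 183 and 12, S100a8 at 242 and 129 and S100a9 at 262 and 182. Dendritic cell genes had a median of 0.26 (8 of 14 higher and 5 lower), the most abundant member in both fractions being the class II invariant chain gene Cd74 at 6522 and 4371. Monocyte and macrophage genes (median -0.09, with Lyz2 highest at 6173 and 5986), mast cell and basophil genes (0.15), and stromal and endothelial genes (0.12) lay within the random range. Only 2 B cell genes and 4 T and NK cell genes passed the filter, the highest being Cd79b at 870 and 749 and Lck at 370 and 399. Glycolysis (-0.02), MHC class I (-0.05) and glutathione and detoxification genes (-0.04) did not stand apart. Cholesterol synthesis genes had a median of 0.14 (17 of 20 higher), niche adhesion and cytokine receptor genes of 0.09 (26 of 36 higher), unfolded protein response genes of -0.12 (14 of 23 lower) and housekeeping genes of -0.13 (14 of 15 lower). These 4 lists and the dendritic cell list each returned to the random range under at least 1 alternative setting, for instance at percentiles 95.2, 96.1, 10.3, 2.95 and 95.7 when means took the place of medians. The counts of 2-fold genes depended on low levels: among genes with a mean of at least 200, 9 were higher and 57 lower. The 2 fractions also differed in sex-linked transcripts, with Xist at 3087 in GFP+ and 6137 in GFP- HSCs and 4 Y-linked genes at a summed 7393 and 5841.

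**Figure D3:**
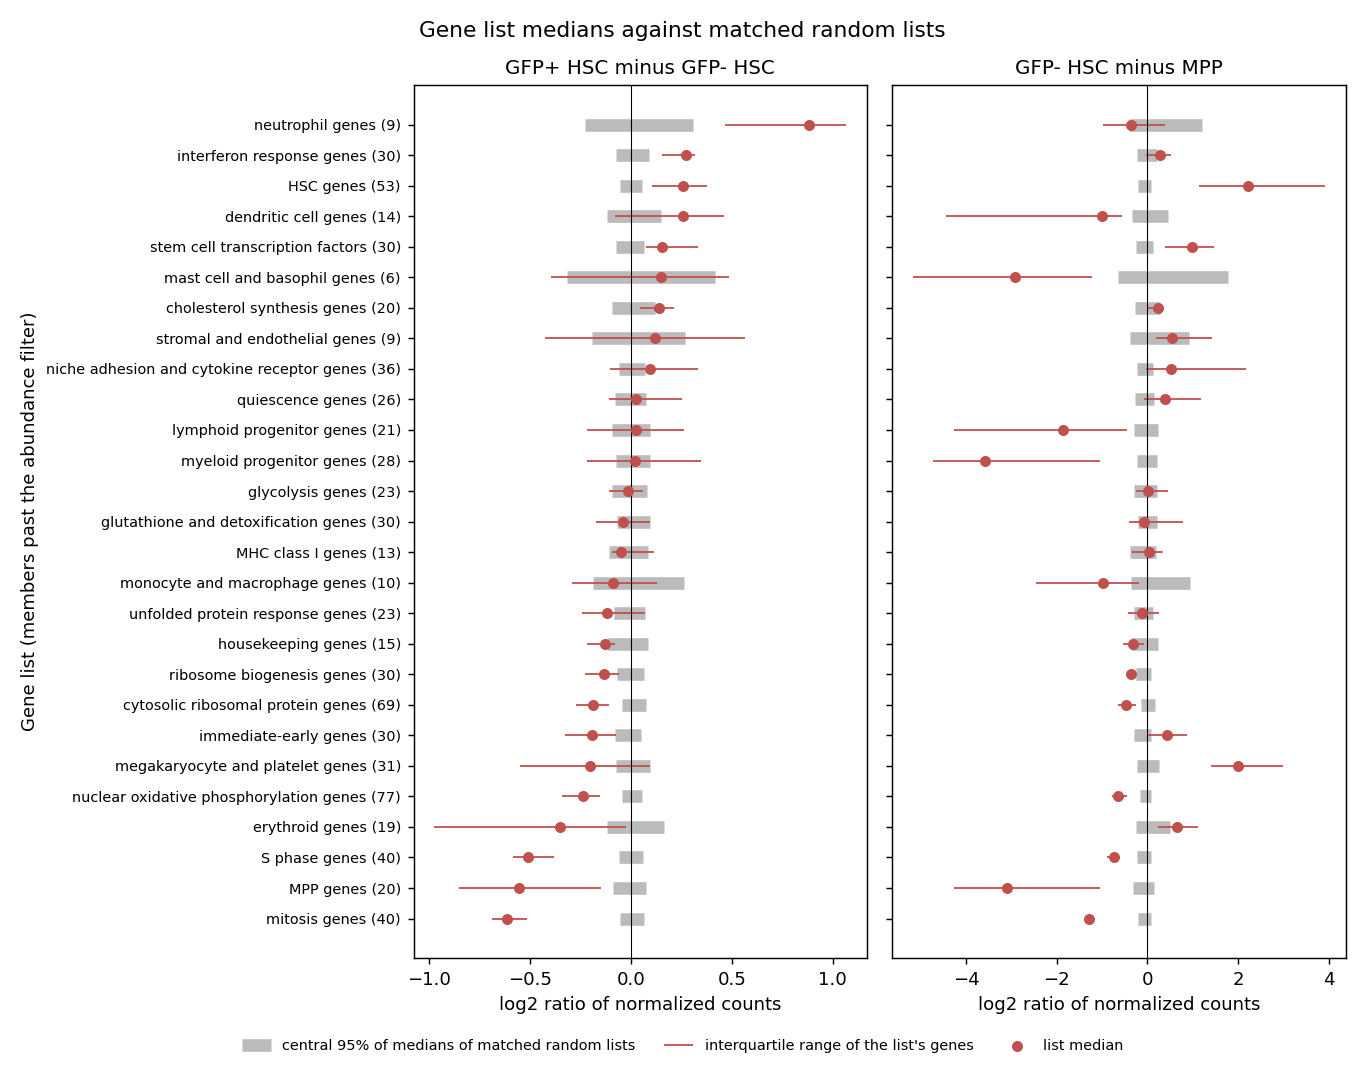
Median log2 ratio of each gene list for GFP+ minus GFP- HSCs (left) and GFP- HSCs minus MPPs (right); points are medians, thin lines the interquartile range of the list's genes, grey bars the central 95% of medians of 10000 matched random lists, and numbers after the names the members counted. Mitosis genes lie at -0.62 and -1.28 and HSC genes at 0.26 and 2.23, while megakaryocyte and platelet genes lie at -0.20 on the left and 2.01 on the right. The scales of the 2 panels differ.

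The comparison of GFP- HSCs with MPPs set the stem cell gate beside the progenitor gate with the reporter off in both. The 2 libraries were much farther apart than the 2 HSC fractions: 1384 genes were at least 2-fold higher and 661 at least 2-fold lower in GFP- HSCs, the Spearman correlation was 0.918 and the median absolute log2 ratio 0.37. HSC genes and genes of megakaryocytes and platelets were higher in GFP- HSCs, with medians of 4.69-fold and 4.03-fold. Genes of MPPs were 8.57-fold and genes of lymphoid progenitors 3.61-fold lower at the median, and genes of myeloid progenitors had a median log2 ratio of -3.58. Mitosis and S phase genes were lower in all 80 members.

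The highest ratios belonged to genes listed at 0 or at low levels in MPPs. Evc2, a part of the Hedgehog pathway at the cilium, stood at 1 in MPPs and 1185 in GFP- HSCs, Sfrp1, a secreted Wnt antagonist, at 1 and 764, and the caveola gene Sdpr at 19 and 3104. Wwtr1, which encodes the Hippo pathway co-activator TAZ, and Cyp26b1, which encodes an enzyme that degrades retinoic acid, were listed at 0 in MPPs and at 618 and 446 in GFP- HSCs. The retinoic acid receptor gene Rarb stood at 2 and 624, the junction gene Jam2 at 5 and 948, Rhoj at 3 and 782, and Matn4 at 1 and 547. At the other end, Dntt, the terminal transferase of early lymphoid cells, stood at 20577 in MPPs and 18 in GFP- HSCs. Kcng1 (909 and 2), Ccdc135 (523 and 1), Chdh (1720 and 16), Igj (2929 and 46), Sema3d (622 and 6), Arpp21 (718 and 8) and Pyhin1 (647 and 8) followed. The basophil protease gene Mcpt8 stood at 530 in MPPs and was listed at 0 in GFP- HSCs, and Siglech, a marker of plasmacytoid dendritic cells, stood at 622 and 7.

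Of the 53 HSC genes, 41 were at least 2-fold higher in GFP- HSCs and 1, the signalling inhibitor gene Socs2 (2402 in MPPs and 652 in GFP- HSCs), at least 2-fold lower. Tgm2 stood at 152 and 11121, Sult1a1 at 24 and 1685, Nupr1 at 12 and 923 and Clca1 at 6 and 963. Stem cell transcription factors had a median of 0.98 with 15 of 30 at least 2-fold higher, including Gata2 at 4005 and 25984 and Mecom at 1220 and 6936. Without the members that other lists share, this median was 0.48. Quiescence genes had a median of 0.38 with 9 of 26 at least 2-fold higher, among them the Notch target gene Hes1 (202 and 3403) and Ndn (87 and 1836). Megakaryocyte and platelet genes were at least 2-fold higher in 24 of 31 cases, as for Vwf at 157 and 7697 and Mmrn1 at 1330 and 19967. Erythroid genes had a median of 0.66 with 7 of 19 at least 2-fold higher, among them Car2 at 17129 and 46482 and Gata1 at 138 and 758. Niche adhesion and cytokine receptor genes had a median of 0.52, with the angiopoietin receptor gene Tek at 105 and 2718 and Tgfbr3 at 316 and 4991. Immediate-early genes had a median of 0.43, with Nr4a1 at 13943 and 50260, and interferon response genes of 0.27, with Ifih1 at 955 and 2304.

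All 20 MPP genes were lower in GFP- HSCs, and 15 were at least 2-fold lower. Of 28 myeloid progenitor genes, 21 were at least 2-fold lower, such as Mpo at 135409 in MPPs and 2758 in GFP- HSCs, Ctsg at 7969 and 159 and the transcription factor gene Irf8 at 8046 and 265. Lymphoid progenitor genes were at least 2-fold lower in 11 of 21 cases, with Rag2 at 354 and 3 and Il7r at 246 in MPPs and listed at 0 in GFP- HSCs. Markers of other blood cells were lower too, with medians of -0.97 for monocytes and macrophages (Csf1r at 1666 and 57), -1.0 for dendritic cells and -2.92 for mast cells and basophils (Hdc at 606 and 36). Mitosis genes had a median of -1.28 with 36 of 40 at least 2-fold lower, and S phase genes of -0.74 with 4 of 40 at least 2-fold lower. Ube2c stood at 3942 and 1044, Ect2 at 5311 and 1573, Uhrf1 at 8051 and 3863 and Rrm2 at 5653 and 2459. Cytosolic ribosomal protein genes (-0.47), ribosome biogenesis genes (-0.35) and nuclear oxidative phosphorylation genes (-0.64) were lower, with all 30 ribosome biogenesis genes below their MPP level, among them Npm1 at 7464 and 4407. With the trend on length and GC content removed, the ribosomal protein and oxidative phosphorylation medians were -0.24 and -0.38. Neutrophil (-0.36), stromal and endothelial (0.55), glycolysis (0.02), unfolded protein response (-0.12), cholesterol synthesis (0.24), MHC class I (0.03), glutathione and detoxification (-0.07) and housekeeping genes (-0.31) lay within the random range. Erythroid genes fell back into that range, at percentile 95.4, with the abundance trend removed, interferon genes at 62.4 by their mean, and quiescence genes at 97.4 without shared members.

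The comparison of GFP+ HSCs with MPPs joined both differences. It held the most genes past the rule of size, with 1636 at least 2-fold higher and 1028 at least 2-fold lower in GFP+ HSCs, and the lowest Spearman correlation, 0.885. HSC genes were 5.81-fold higher at the median, MPP genes 18.8-fold lower, mitosis genes 3.69-fold lower and S phase genes 2.43-fold lower. All 40 mitosis genes and 33 of 40 S phase genes were at least 2-fold lower in GFP+ HSCs. Megakaryocyte and platelet genes were 3.11-fold higher at the median, and 21 of 31 were at least 2-fold higher.

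Evc2, Sfrp1, Wwtr1, Sdpr, Cyp26b1, Rhoj, Jam2 and Rarb were again among the 10 highest ratios. They were joined by Evc, a partner of Evc2, and by the ephrin gene Efna1, both listed at 0 in MPPs and standing at 691 and 618 in GFP+ HSCs. The lowest ratios again included Dntt, Kcng1, Sema3d, Ccdc135 and Mcpt8. Cd48 was 121-fold lower in GFP+ HSCs, and the lymphocyte receptor gene Btla stood at 666 in MPPs and was listed at 0 in GFP+ HSCs. Cst7 stood at 1676 and 13 and Tespa1 at 1549 and 12. Myeloid progenitor genes had a median of -3.19 (Elane at 16125 and 425, Ms4a3 at 2059 and 46) and lymphoid progenitor genes of -1.40 (Ccr9 at 480 and 10). Stem cell transcription factors had a median of 1.24, or 0.63 without members shared with other lists, and quiescence genes of 0.43. Dendritic cell (-0.94), monocyte and macrophage (-1.0), and mast cell and basophil genes (-3.81) were lower. Cytosolic ribosomal protein genes (-0.67), ribosome biogenesis genes (-0.50) and nuclear oxidative phosphorylation genes (-0.86) were lower, the first and the last at -0.35 and -0.52 with the trend on length and GC content removed. Neutrophil (0.75), stromal and endothelial (0.77), glycolysis (0.12), unfolded protein response (-0.03), MHC class I (-0.01), glutathione and detoxification (-0.04) and housekeeping genes (-0.43) lay within the random range. Interferon response (0.50), erythroid (0.73), cholesterol synthesis (0.45), niche adhesion and cytokine receptor (0.48) and immediate-early genes (0.22) lay above it, but returned to it, at percentiles 90.1, 59.7, 74.4, 88.7 and 92.5, by the mean for the first 3, without shared members for the fourth and against unmatched lists for the fifth.

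The design also places the 3 libraries in an order, from MPPs through GFP- HSCs to GFP+ HSCs. Along it, 21 genes were at least 2-fold higher at each step and 55 at least 2-fold lower at each step. Tenc1, which encodes a tensin of focal adhesions, stood at 35, 2300 and 4632, the RNA-binding protein gene Igf2bp2 at 74, 703 and 1602, the imprinted non-coding RNA gene Meg3 at 1, 188 and 421, and Gimap3 at 57, 349 and 842. On the descending side, Dntt stood at 20577, 18 and 2, Cd48 at 7744, 168 and 64, Cst7 at 1676, 43 and 13, and Btla and Sema3d were listed at 0 in GFP+ HSCs. Genes at least 2-fold higher in GFP- HSCs than in MPPs were also higher in GFP+ than in GFP- HSCs in 76.8% of cases, by a median log2 ratio of 0.23, against 51.7% of all genes. Genes at least 2-fold lower in GFP- HSCs were lower again in GFP+ HSCs in 67.6% of cases, with a median of -0.27. Genes at least 2-fold apart at both steps but in opposite directions numbered 16 with the lowest level in GFP- HSCs, among them Igj and Irf2bp2, and 13 with the highest level there, among them Pf4 and Gata1.

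Independent lists of the observed sizes would share 5.67 genes on the ascending and 5.75 on the descending side, and 2.71 and 12 for the genes lowest and highest in GFP- HSCs. These numbers take no account of level, although genes 2-fold apart were concentrated at low levels in both steps. With a mean of 50 to 200, 5.22% of genes were 2-fold apart between the HSC fractions and 44.5% between GFP- HSCs and MPPs. From a mean of 5000 up, 0.294% and 6.76% were. The numbers for independent lists may therefore be too small. Both steps use the GFP- library, so its chance deviations enter them with opposite signs: simulated libraries with no difference gave 0 genes past both steps and a Pearson correlation of -0.50 between the steps. The simulated noise was normal, with its width taken from the median spread between the GFP+ and GFP- libraries at each level; it holds no genes of unusual spread and no variation between repeated sorts, so the 0 is no measure of what separate libraries of the same cells would give. The observed correlation across genes was 0.36 (Spearman 0.44), and the covariance was 0.12 against -0.03 in the simulation. Genes are not independent replicates, and the GFP- library could not be divided to remove the sharing. The ascending count rested on low levels, with 4 genes left among those with a mean of at least 200.

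**Figure D4:**
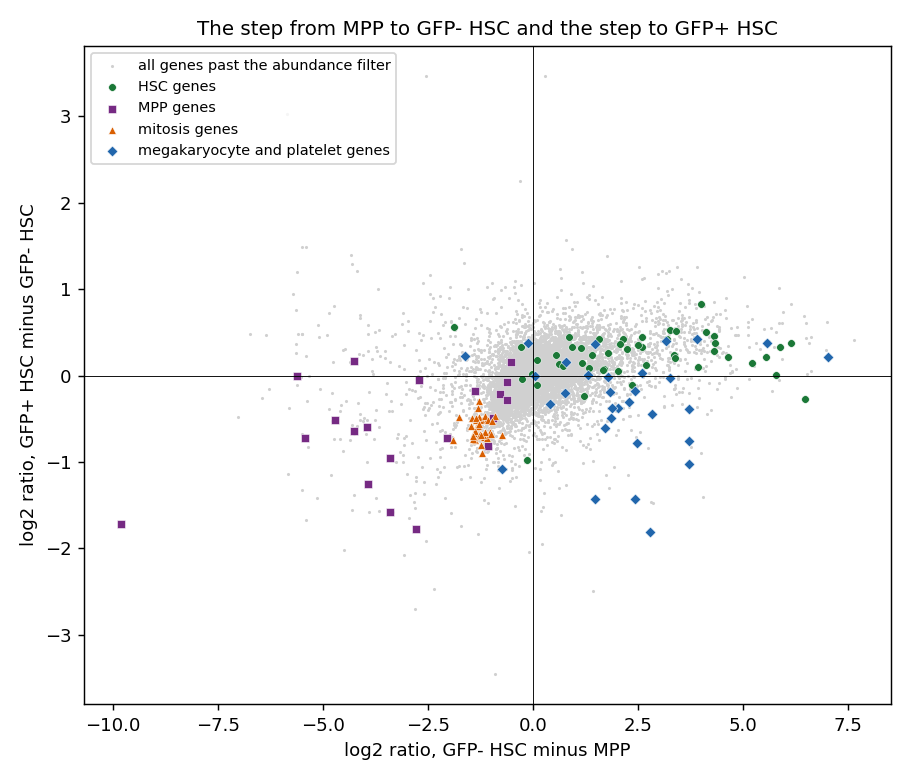
Log2 ratio of GFP+ to GFP- HSCs (vertical) against log2 ratio of GFP- HSCs to MPPs (horizontal) for 11951 genes in grey, with 4 gene lists in colour; each point is 1 gene. Mitosis genes cluster to the left and below 0, HSC genes mostly to the right and slightly above 0, and megakaryocyte and platelet genes to the right on both sides of 0, with Pf4 and Gata1 among the lowest.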

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

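The settings for length and GC content and for the filter on 2 libraries were chosen after seeing the data, and the others before the data were examined. With 1 library per population, leaving out a replicate was not possible, and no paired analysis was possible because there are no replicate numbers to pair. Counting intervals could not be made, so depth remains an unknown limit on low genes. Scaling moved the median ratio of all genes by less than 0.1 on the log2 scale, at most to 0.09. HSC, MPP, S phase, mitosis, megakaryocyte, myeloid and lymphoid list medians that stood apart kept their sign and place outside the random range in every setting run. Of 777 pairs of a list that stood apart and a setting, 26 returned to the random range, over 16 list medians. Counts of genes differed most, as the construction of the filters and thresholds implies. For GFP+ against GFP- HSCs, genes higher and lower numbered 23 and 62 with a pseudocount of 20, 164 and 194 with a minimum of 10, 9 and 57 with 200, 356 and 359 with no filter, and 4 and 7 at 4-fold, against 49 and 104. The excess of lower over higher genes was thus small without a filter. For GFP- HSCs against MPPs, genes higher numbered 854 with a minimum of 200, 2320 with no filter and 601 at 4-fold, and genes lower 1172 with no filter and 240 at 4-fold. For GFP+ HSCs against MPPs they numbered 1049, 2647 and 702 higher, and 1576 and 307 lower. Genes rising at both steps numbered 12 with a pseudocount of 20, 59 with a minimum of 10, 4 with 200, 65 with no filter, 13 with the abundance trend removed and 0 at 4-fold. Genes falling at both steps numbered 31 with a pseudocount of 20, 33 with a minimum of 200 and 4 at 4-fold. Spearman correlations with minimums of 10 and 200 were 0.992 and 0.986 for the 2 HSC fractions, 0.935 and 0.892 for GFP- HSCs against MPPs, and 0.911 and 0.847 for GFP+ HSCs against MPPs; without a filter the last pair gave 0.951 and 0.937. For mitosis genes in GFP- HSCs against MPPs, the median was -1.21 at the same total, -1.22 at the same upper quartile and -1.18 with the abundance trend removed. In GFP+ HSCs against MPPs it was -1.81 at the same total and -1.80 with the trend removed, and S phase genes in GFP- HSCs against MPPs lay at -0.63 with the trend removed. The sex gene list between the 2 HSC fractions reversed from 0.24 to -0.11 by its mean, since the rows of Xist and Tsix went against 4 Y-linked genes; Tsix overlaps Xist on the opposite strand, so its row cannot be counted apart from Xist. The cause of the other shifts was not tested.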

Other observations

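The imprinted, retinoic acid, Gimap and histone gene lists were drawn up after the data were seen, and members whose values had prompted them were left out of their tests. The remaining members are not thereby independent of those left out, since genes of the same family or locus can move together. The tests on carried-over MPPs, neutrophil-lineage and stromal cells and on retinoic acid genes were chosen after the results they bear on were seen, and the genes named for these lists were picked after their values were seen.

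Imprinted genes, which are expressed from 1 parental copy and include several growth regulators, mostly followed the order of the populations. Of 17 members past the filter, without Meg3, Cdkn1c and Ndn, 14 were higher in GFP- HSCs than in MPPs, 11 of them at least 2-fold, with a median log2 ratio of 1.10 at percentile 99.97 of matched random lists. The growth factor adaptor gene Grb10 stood at 215 in MPPs, 5321 in GFP- HSCs and 6355 in GFP+ HSCs, Phlda2 at 19, 239 and 264, Peg3 at 2, 60 and 119 and Dlk1 at 63, 162 and 250. Between the HSC fractions, 14 of 17 were higher in GFP+ HSCs, 0 of them 2-fold, with a median of 0.21 at percentile 99.6. Of all genes at least 2-fold higher in GFP- HSCs than in MPPs, 76.8% were higher in GFP+ HSCs, by a median of 0.23. The random lists were matched on mean level only, so this step does not set imprinted genes apart from other genes high in HSCs. Mest and Gnas ran the other way in both comparisons. Igf2r (1441 in MPPs, 1127 in GFP- and 1638 in GFP+ HSCs) did so from MPPs to GFP- HSCs, and Asb4 (10, 158 and 153) between the HSC fractions. The hypothesis that imprinted genes are higher the farther a fraction lies from MPPs may hold for these libraries. Nothing here makes the step from GFP- to GFP+ HSCs particular to them, and replicates would be needed.

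Genes of the retinoic acid pathway differed between the gates but not clearly between the reporter fractions. Without Rarb, Cyp26b1 and members of the HSC list, 8 genes had a median of 0.77 for GFP- HSCs against MPPs, at percentile 99.6, with 5 higher, 3 of them at least 2-fold, and 3 lower, 1 of them at least 2-fold. The retinaldehyde dehydrogenase gene Aldh1a1 stood at 103 in MPPs, 3795 in GFP- HSCs and 3700 in GFP+ HSCs, and Rdh10 at 192, 594 and 879, whereas Dhrs3 stood at 2218, 438 and 389. For GFP+ against GFP- HSCs their median was 0.060, at percentile 70.4, with 5 higher and 2 lower, which does not decide. Gimap genes other than Gimap3 had a median of 0.27 for GFP+ against GFP- HSCs, at percentile 99.7, with 6 of 7 higher, such as Gimap4 at 618 and 394, and Gimap7 lower at 40 and 46. Gimap1, Gimap4, Gimap5, Gimap6 and Gimap8 were also higher in GFP- HSCs than in MPPs, and Gimap7 and Gimap9 lower. All genes at least 2-fold higher in GFP- HSCs than in MPPs had a median of 0.23 between the HSC fractions. With random lists matched on mean level only, Gimap genes are not set apart from other genes high in HSCs. Replication-dependent histone genes other than Hist1h1b had a median of -0.074 at percentile 11.8 in 13 members, which does not decide either. Most rows of that list lay below the abundance filter, so the 13 stand for only a part of it. Among them, Hist1h4d (134 in GFP+ and 308 in GFP- HSCs) and Hist1h1a (37 and 82) were at least 2-fold lower. Xist stood at 2262 in MPPs, 6137 in GFP- HSCs and 3087 in GFP+ HSCs, and 4 Y-linked genes summed to 6042, 5841 and 7393. The labels do not give the sex of the mice, and a different mix of male and female cells in the libraries, which was not tested, would bear on every comparison here. The median log2 ratio of the 6 sex gene rows, of which Tsix overlaps Xist on the opposite strand, was 0.24 for GFP+ against GFP- HSCs, 0.01 for GFP- HSCs against MPPs and 0.24 for GFP+ HSCs against MPPs.

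The first pattern weighed was that MPP genes and cell cycle genes were lower in GFP+ than in GFP- HSCs. Were MPPs carried into the GFP- sort the source, the 5 most abundant transcripts restricted to MPPs would give the same share of MPP cells as the lists. Pooled, so that Mpo weighs most, they gave 0.631%. Singly they gave 0.00603% (Mpo), 0.0778% (Dntt) and up to 3.96% (Plac8). The list medians, which weigh each gene alike and so are an unlike measure to the pooled share, were 4.79% over MPP genes and 24.0% over cell cycle genes. Mpo, Dntt, Flt3 and Plac8 are also members of the MPP list. All 5 single shares lay below both medians, which argues against the sorted MPPs as a whole as that source. Over all 35 transcripts restricted to MPPs the median was 1.69% (interquartile range 0.239% to 3.34%), nearer to that of the MPP genes (1.05% to 10.97%), so for these a subset of MPPs lacking Mpo and Dntt, or other progenitors, stays open. Transcript length and GC content are argued against for the cell cycle genes, whose pooled median of -0.55 lay at percentile 0 of lists matched on both. A biological difference between the reporter groups stays open and was not tested apart from these transcripts.

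A second pattern was that ribosomal protein and oxidative phosphorylation genes, which have short transcripts, were lower in GFP+ than in GFP- HSCs. Their pooled median of -0.22 lay at percentile 0 of random lists matched on expression, length and GC content, whose own median was -0.06. Length and GC content may therefore account for part of the difference and not for the whole. With the abundance trend removed the pooled median was -0.23, which argues against abundance-dependent scaling. A difference in RNA quality between the libraries and a biological difference between the reporter groups stay open.

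The third pattern was that neutrophil genes and Col1a1 were higher in GFP+ than in GFP- HSCs, although the LSK gate removes mature neutrophils and stroma. Neutrophil-lineage cells or their free RNA in the GFP+ sort are a possible explanation: 8 of 9 neutrophil genes were higher, such as Ngp at 499 against 165, but Padi4, the most abundant member, was 2833 against 2959 and is also at 3799 in MPPs, so its baseline hides a small share and the source cannot be told apart from expression by stem cells. Stromal cells as the source of Col1a1 cannot be told apart from other sources: Col3a1, Sparc and Dcn summed to 116 in GFP- and 33 in GFP+ HSCs, a difference of -83 that rests on Sparc (108 and 33), since the others were at 5 or less, and Cxcl12 was lower in GFP+ HSCs too (29 against 187), whereas Col1a2 was higher, at 679 against 457. No biological explanation was tested for either.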
